A study of Arabidopsis thaliana with 6 samples.

How the data were processed

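RNA was measured in 6 libraries, 3 of WT (Columbia) and 3 of hrlp-2, from the aerial parts of 9-day-old seedlings. Plants were grown at 23 ± 2 °C, and libraries were made with a directional (strand-marking) kit from total RNA, per the labels' protocols. STAR 2.7.3a and the TAIR10 genome build are named in the submitters' processing notes. The read counter, the annotation, the strand setting and any filter are not given in the sources used here. Groups and replicate numbers were taken from the sample titles.

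The authors deposited 1 table per library, whose values are in read counts scaled to a common library total (CPM). The columns sum to between 1000000.4 and 1000007.8, and most low values lay on 1 step per library whatever the gene, which values scaled by gene length would not. The step was found as the spacing that placed most values under 2 CPM on whole multiples, within 0.0051 CPM. It was 0.0397 to 0.0499 CPM per read, or 20.1 to 25.2 reads per CPM. Between 88.0% and 89.5% of the low values lay on the steps, against 20.5% to 25.7% by chance. Since the rest did not, whole reads could not be recovered for every gene, and no count model was used as the main test. The design fixed before the data were examined had assumed read counts and a quasi-likelihood count model, and the unit required limma in its place. Estimated reads cover counting error only, and the sources used here mention no molecular identifiers.

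Each table held 22759 named rows and 1 row without a name, which was left out. Rows at 0 numbered 1294 to 1534 per library, and 244 rows were at 0 in all libraries. Names were matched to loci through the RefSeq gene table of TAIR10.1, which placed 19499 rows and left 3260 without a locus. Of these, 20 rows carry numbers that spreadsheet software makes from gene names that look like dates, and their names were not restored. No chloroplast or mitochondrial locus was among the matched rows, so the planned share of organelle reads was not analysed here.

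The main comparison used limma 3.58.1 in R 4.3.3. Rows with at least 0.5 CPM in at least 3 libraries were kept (18643 rows). Values were divided by trimmed-mean-of-M factors (TMM, 30% of M and 5% of A values trimmed on each side, unweighted), which ranged from 0.9888 to 1.0131. A pseudocount of 0.5 CPM was added before log2 transformation. Moderated tests with an intensity trend were two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are on the log2(CPM + 0.5) scale, which understates the change of weakly expressed genes. With 3 against 3 libraries an exact permutation test of 1 gene cannot go below p = 0.1.

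The 25 gene lists were fixed before the data were examined, with 332 members, of which 287 had a row. The list members were matched by locus, and 1 match made through a synonym that names another gene was dropped after its values were seen. The 22 lists with at least 3 tested members were tested with camera at a preset correlation of 0.01. An estimated correlation per list and fry were run beside it. Genes were named by a rule fixed in advance. It covered HRLP, SR45 and FLC, the 10 largest rises and 10 largest falls among called genes whose groups did not overlap and whose mean log2 value was at least 1, up to 4 called members of each list by size of change, the FLC clade and floral integrators whether called or not, and the tested neighbours of HRLP. Outside that rule, TGG1, AOS, LHCB1.1, RBCS1B, UBP1C, the root and heat shock markers that did not pass and the family and touch-list members were named after their values were seen. Called genes were placed along the chromosomes in windows of 50 tested loci and set against 1000 shuffles.

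Libraries of the same group were checked for duplicates with a chi-square statistic on estimated reads. Its median per gene was 0.785 to 0.903 within groups, against 0.455 from counting noise, so no pair was merged. Its mean per gene was 13.982 and 11.794 for WT replicate 3 against WT replicates 1 and 2. The other pairs within groups had means of 2.265 to 2.511, so WT replicate 3 departed from the other WT libraries for some genes. The first principal component held 42.3% of the variance and separated the groups.

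The functions were tested on simulated reads for the real genes and depths, with 200 changed genes among 18657 tested in a comparison of 3 against 3. All 50 genes changed 4-fold and all 50 changed 2-fold were recovered, as were 44 of 50 at 1.5-fold and 15 of 50 at 1.2-fold, with 8 unchanged genes called. The changed genes all had a mean of at least 2 CPM, and every gene was given the same dispersion of 0.003. Recovery of weaker genes, or of genes with a wider spread, was therefore not tested. The alternatives were limma-voom on estimated reads, 2 other scalings (relative log expression and upper quartile), no filter and a filter of 1 CPM, the replicate number as a block, leaving out each library, 2 other set tests and windows of 25 and 100 loci. Chosen after the data were seen were pseudocounts of 0.1 and 1, the deposited CPM without rescaling, noncoding transcripts left out, fry's mixed p, the scan of gene families and a list of touch-inducible genes. Checks of that list without the genes that prompted it were added last. For the touch list, a check of the spread between replicates was replaced after its value was seen (0.99 times that of matched genes).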

Results

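RNA sequencing compared Arabidopsis thaliana seedlings of the Columbia accession (wild type, WT) with seedlings of the mutant line hrlp-2. HRLP (AT2G44710) encodes an hnRNP R-like RNA-binding protein with RNA recognition motifs. Each group had 3 libraries, each described in the labels as a biological replicate, made from total RNA of the aerial parts of seedlings grown for 9 days in long days of 16 h light and 8 h dark. The deposited values were read counts scaled to a common library total (CPM) for 22759 named genes and noncoding transcripts. The spacing of the low values put 1 CPM at 22.1 to 23.5 reads in the WT libraries and at 20.1 to 25.2 reads in the hrlp-2 libraries. Values below are CPM ± SD over the 3 libraries of a group, and adjusted p-values come from limma on log2(CPM + 0.5) with Benjamini-Hochberg adjustment over the 18643 rows tested.

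The HRLP transcript was lower in hrlp-2 but remained present in every mutant library. HRLP lies on chromosome 2 of TAIR10.1 at 18432686 to 18437221, on the plus strand. It measured 31.15 ± 1.65 CPM in WT (n = 3) and 16.56 ± 0.601 CPM in hrlp-2 (n = 3), which is 53.2% of the WT mean. The 3 hrlp-2 libraries lay between 15.88 and 17.03 CPM and the 3 WT libraries between 30.03 and 33.04 CPM. The log2 fold change was -0.87 (SE 0.0648, limma adjusted p = 4.95e-12). A total per gene does not tell which part of the transcript the reads came from. The nearest tested neighbours on each side did not pass the test. AT2G44700 measured 0.943 ± 0.285 and 0.797 ± 0.294 CPM (adjusted p = 0.729), and AT2G44730 measured 15.95 ± 0.704 and 16.13 ± 0.683 CPM (adjusted p = 0.785). SR45, a serine/arginine-rich splicing factor, measured 36.14 ± 0.972 CPM in WT and 33.39 ± 1.26 CPM in hrlp-2 (adjusted p = 0.25).

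FLC, the MADS-box gene that represses flowering, rose 2.62-fold in hrlp-2. It lies on chromosome 5 of TAIR10.1 at 3173382 to 3179448, on the minus strand, and went from 4.45 ± 0.396 CPM in WT to 12.24 ± 0.333 CPM in hrlp-2 (n = 3 each, log2 fold change 1.39, SE 0.11, adjusted p = 2e-11). SOC1, which promotes the transition to flowering and is repressed by FLC, fell from 25.24 ± 0.606 to 20.14 ± 0.459 CPM (adjusted p = 0.000736). FT, the mobile flowering signal, measured 1.33 ± 0.238 CPM in WT and 0.827 ± 0.108 CPM in hrlp-2 and did not pass the test (adjusted p = 0.156). SVP, another floral repressor, passed at 85.26 ± 3.16 against 77.82 ± 0.673 CPM (adjusted p = 0.0403).

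Of the 6 tested members of the FLC clade, 1 rose (FLC) and 1 fell. The member that fell was FLM, at 41.23 ± 0.865 CPM in WT and 35.52 ± 1.62 CPM in hrlp-2 (adjusted p = 0.00697). MAF2 (24.37 against 22.68 CPM), MAF3 (8.29 against 9.37 CPM), MAF4 (3.04 against 2.65 CPM) and MAF5 (3.15 against 2.80 CPM) did not pass. The counts adjusted over the list alone were again 1 and 1. The clade's median log2 fold change was -0.10 and its mean 0.18, so they differed in sign, and the camera test gave an adjusted p of 0.681 with direction up. Fry, which does not compare a list with other genes, called the clade up (adjusted p = 0.0367). The FLC clade median ran from -0.13 to -0.02 when single libraries were left out. Among floral integrators and meristem identity genes, 0 rose, 2 fell (SOC1 and SVP) and 9 of the 11 tested did not pass. Adjusted over the list alone, 5 fell: SOC1, SVP, SPL3 (8.15 against 6.49 CPM), SPL4 (10.23 against 8.35 CPM) and FUL (1.01 against 0.463 CPM). SPL5 (1.62 against 2.27 CPM), SPL9 (11.44 against 10.61 CPM), AGL19 (0.887 against 0.763 CPM), AGL24 (7.30 against 7.20 CPM) and FD (1.13 against 1.11 CPM) did not pass in either count. AP1 was listed at 0 in every library, and TSF, LFY, CAL, SPL15, AGL42 and TFL1 stayed under the expression filter. The list as a whole missed the camera threshold (adjusted p = 0.0622, direction down, and adjusted p = 0.221 with an estimated correlation), but passed without the expression filter (adjusted p = 0.0425). Fry called this list down (adjusted p = 0.00702). The call of FLM ended without hrlp-2 replicate 3 (adjusted p = 0.0588), and that of SVP ended in 5 of the 6 fits that left out 1 library, with adjusted p-values up to 0.15; FUL passed without hrlp-2 replicate 3 or noncoding transcripts and SPL3 without hrlp-2 replicate 1.

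**Figure D1:**
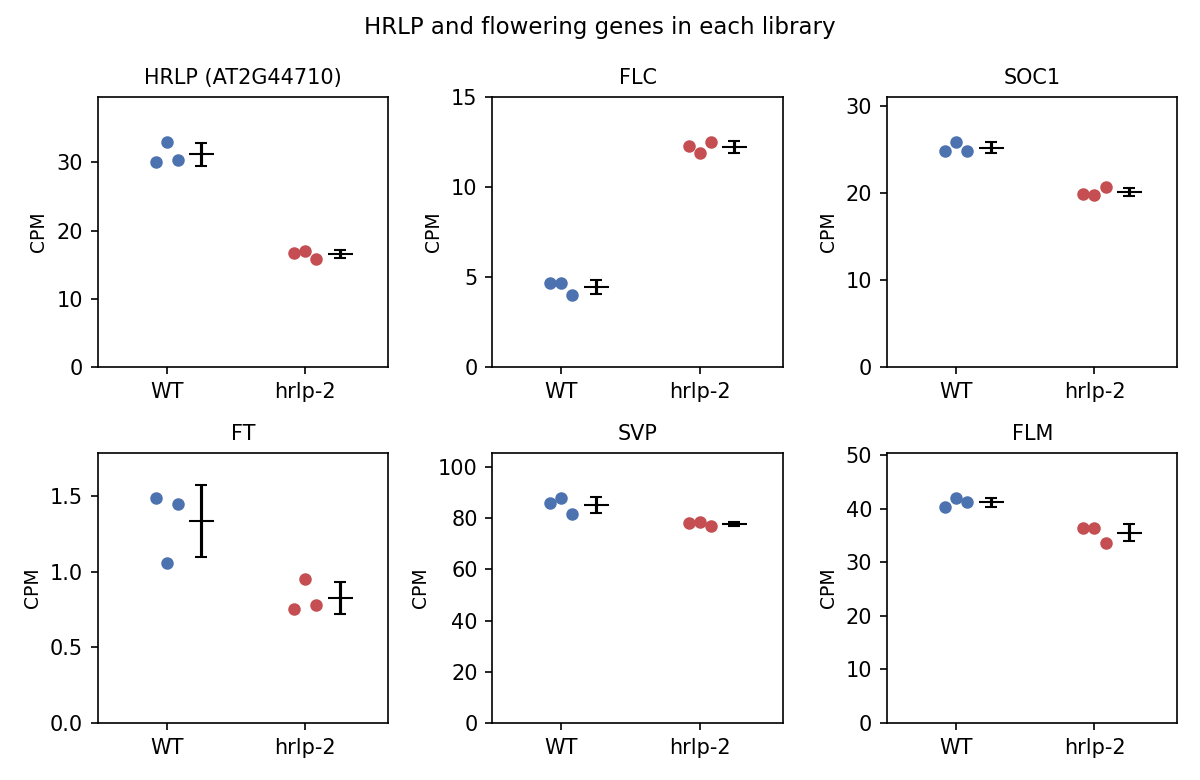
CPM of HRLP, FLC, SOC1, FT, SVP and FLM in each WT (blue) and hrlp-2 (red) library, with the group mean and SD in black. FLC lies near 12.24 CPM in hrlp-2 and 4.45 CPM in WT, while HRLP lies at 16.56 against 31.15 CPM and the FT values of the groups stay within 1.5 CPM.

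In the regulators upstream of these genes, the passing changes were small. Among photoperiod genes, the photoreceptor genes CRY2 (135.6 ± 1.90 to 151.5 ± 0.544 CPM, adjusted p = 2.79e-05) and PHYA (52.12 ± 3.65 to 59.82 ± 1.57 CPM, adjusted p = 0.000865) rose. CDF3, a repressor of CO transcription, fell from 32.0 ± 1.16 to 25.31 ± 1.18 CPM (adjusted p = 0.000182), and GI fell from 117.0 ± 3.16 to 106.7 ± 2.01 CPM (adjusted p = 0.0192). These were 2 rises and 2 falls among 11 tested, and 2 and 3 adjusted over the list alone. Among 10 autonomous-pathway genes and other FLC repressors, 1 fell (LD, 22.38 to 19.15 CPM, adjusted p = 0.0361), and none passed adjusted over the list alone. Among 11 FLC activators, 2 fell, PIE1 (39.52 to 33.88 CPM) and SUF4 (31.72 to 27.2 CPM), and the same number adjusted over the list alone. Among 9 vernalization and PRC2 genes, 1 fell in both counts, LHP1 (18.22 to 15.16 CPM, adjusted p = 0.0287). None of these 4 lists was called by camera (adjusted p = 0.313, 0.12, 0.0532 and 0.597). By its directional p, fry called only the FLC activators among them, down (adjusted p = 0.0264). Falls among the photoperiod genes numbered 1 to 4 when single libraries were left out; the call of LD ended in 5 such fits (adjusted p up to 0.19), that of LHP1 in 4 (up to 0.137), both also without the expression filter, and those of GI (up to 0.093), PIE1 (up to 0.0567) and SUF4 (up to 0.0963) in 2 fits each. The list FLC activators passed camera with upper-quartile scaling (adjusted p = 0.0469), the deposited CPM not rescaled (0.0466), no expression filter (0.0425), and without WT replicate 2 (0.0422) or hrlp-2 replicate 1 (0.0399), against adjusted p = 0.221 with an estimated correlation.

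Changes across the transcriptome were ranked among called genes whose groups did not overlap and whose mean log2 value was at least 1. Of these, AT3G29633, the ethylene response factor gene ERF012, the mitochondrial carrier gene PUMP4 and XTH22 rose most, and 3 plant defensin genes fell most. AT3G29633, which encodes an uncharacterized protein, went from 0.31 ± 0.14 to 8.70 ± 0.871 CPM (11.6-fold, adjusted p = 5.42e-16). This and the other folds given here are on the log2(CPM + 0.5) scale, which understates changes at low CPM. ERF012 rose 6.51-fold, from 1.2 ± 0.243 to 10.39 ± 1.22 CPM. PUMP4 rose 4.53-fold to 20.88 ± 1.22 CPM. XTH22, a touch-inducible cell wall enzyme gene, rose 4.49-fold from 13.03 ± 1.22 to 59.11 ± 0.946 CPM. ACS6, an enzyme gene of ethylene synthesis, rose 3.93-fold to 43.9 ± 1.19 CPM. The other genes among the 10 largest rises were CAF1-9 (3.10-fold), QQS (2.98 to 9.65 CPM), the zinc finger gene SZF1 (2.84-fold), the defence marker PR1 (2.75-fold) and the expansin-like gene EXLA1 (2.72-fold).

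The defensin genes PDF1.2C, PDF1.2A and PDF1.3 were 14.4-fold, 8.30-fold and 8.09-fold lower in hrlp-2. PDF1.2C went from 13.18 ± 1.601 to 0.477 ± 0.341 CPM (adjusted p = 4.14e-16). These copies are close in sequence, so how reads were divided among them is uncertain. Summed with PDF1.2B, the 4 rows went from 36.69 ± 3.24 to 2.59 ± 0.985 CPM. The ratio of these CPM means was 14.1. It does not compare with the folds of single rows, which are on the log2(CPM + 0.5) scale and understate changes at low CPM. The noncoding transcript AT5G45472.4 was 4.36-fold lower, at 10.68 ± 2.85 against 2.40 ± 1.75 CPM. AT1G55673, an uncharacterized protein gene, was 4.08-fold lower, with a wide spread in WT (151.6 ± 63.3 CPM against 34.47 ± 7.71 CPM). The 10 largest falls in this ranking went on with the zinc finger gene AT1G29560 (2.74-fold), the tyrosine aminotransferase gene TAT3 (2.66-fold) and the glycosyl hydrolase gene AT4G16260 (2.61-fold). Last came NFYC10 (2.40-fold) and the receptor-like protein gene AtRLP31 (2.32-fold). Called rows outside the ranking fell further than AT1G29560 (log2 fold change -1.45), among them AT2G08480.1 (-2.65), PDF1.2B (-1.92) and NDC80 (-1.54).

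In total 2114 rows were higher and 1697 lower in hrlp-2 (limma, adjusted p threshold 0.05), which is 20.4% of the 18643 tested. Most of these changes were small. The median absolute log2 fold change of the called rows was 0.23, and 42 rows rose and 41 fell by at least 2-fold, on the log2(CPM + 0.5) scale that understates changes of weakly expressed genes. Noncoding transcripts were among these falls, such as AT2G08480.1 and AT5G45472.4. The groups did not overlap for 6293 rows (33.8%), against 10% by chance for 3 against 3. The share of higher calls depended on the scaling: 55.5% of calls were higher in hrlp-2 with TMM factors, 45.4% (1685 higher, 2028 lower) with upper-quartile factors and 44.6% (1639 higher, 2035 lower) with the deposited CPM not rescaled. With limma-voom on estimated reads, the rows past 2-fold numbered 83 higher and 98 lower.

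Glucosinolate genes, which make and break down the sulfur-rich defence compounds of the cabbage family, rose as a group. Of 14 tested, 11 rose and 0 fell, and the counts were the same adjusted over the list alone. CYP79B2 rose from 28.84 ± 0.901 to 39.65 ± 2.21 CPM and CYP79B3 from 33.1 ± 0.821 to 44.78 ± 1.59 CPM (adjusted p = 5.89e-08 and 3.62e-08). The regulator gene MYB51 rose from 6.49 to 8.52 CPM and the biosynthesis gene CYP79F1 from 142.8 ± 3.22 to 180.9 ± 6.79 CPM. The myrosinase gene TGG1 rose from 1983 ± 8.79 to 2325 ± 25.6 CPM. The list was called up by camera (adjusted p = 1.09e-11), with adjusted p = 0.0899 with an estimated correlation. The call of MYB51 ended without hrlp-2 replicate 3 (adjusted p = 0.0726).

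Cold, drought and abscisic acid genes also rose, 9 of 14 tested with 0 falling, and 10 adjusted over the list alone. The cold-regulated genes COR15A (245.9 ± 2.88 to 339.5 ± 2.13 CPM, adjusted p = 7.03e-16) and COR15B (299.2 ± 6.50 to 408.6 ± 2.89 CPM, adjusted p = 5.42e-16) were among them. The cold-induced transcription factor gene CBF2 rose from 1.71 ± 0.364 to 3.43 ± 0.503 CPM, and NCED3, an enzyme gene of abscisic acid synthesis, from 3.08 ± 0.299 to 4.76 ± 0.523 CPM. Camera called the list up (adjusted p = 1.24e-10), with adjusted p = 0.0652 with an estimated correlation.

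Of 14 tested salicylic acid and defence genes, 6 rose and 0 fell, and 7 rose adjusted over the list alone. PR1 went from 2.22 ± 0.288 to 6.86 ± 0.510 CPM (adjusted p = 2.7e-09). CBP60G, a transcriptional regulator of salicylic acid synthesis, went from 5.49 ± 1.15 to 13.43 ± 1.18 CPM (adjusted p = 1.1e-09). WRKY70 went from 32.39 ± 0.106 to 52.11 ± 2.02 CPM and PR2 from 8.24 ± 0.503 to 11.13 ± 1.34 CPM. Camera gave adjusted p = 0.000241, and 0.0899 as the adjusted p with an estimated correlation.

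Jasmonate and wounding genes split. Of 18 tested, 6 rose and 3 fell, and 9 rose and 3 fell adjusted over the list alone. The rises included the jasmonate synthesis gene AOS (184.9 ± 4.87 to 224.9 ± 1.6 CPM) and the storage protein gene VSP2 (34.48 ± 2.61 to 51.45 ± 1.09 CPM). The falls were PDF1.2A (11.65 ± 1.03 to 0.967 ± 0.335 CPM), PDF1.2B (3.20 ± 0.590 to 0.490 ± 0.288 CPM) and VSP1 (6.04 ± 0.233 to 4.44 ± 0.996 CPM, adjusted p = 0.0392). PDF1.2A and PDF1.2B are markers of the joint jasmonate and ethylene response. The median log2 fold change was 0.14 and the mean -0.14, so they differed in sign. The camera call was up (adjusted p = 0.0469), with adjusted p = 0.221 with an estimated correlation. The list's call ended in 3 fits without 1 library (adjusted p up to 0.0836, without hrlp-2 replicate 1), with a pseudocount of 1 and without noncoding transcripts, and that of VSP1 in 4 fits without 1 library, with adjusted p-values up to 0.282, and without the expression filter.

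Nuclear photosynthesis genes shifted upward by small amounts, with 13 of 24 rising and 2 falling, in both adjustments. LHCB1.4 rose from 1249 ± 62.3 to 1373 ± 17.7 CPM, LHCA2 from 3813 ± 147 to 4181 ± 23.7 CPM (1.11-fold, adjusted p = 2.22e-07), PSBO1 from 3850 ± 77.4 to 4172 ± 24.7 CPM and LHCB4.1 from 4190 ± 10.6 to 4533 ± 17.1 CPM. The members that fell were LHCB1.1 (12260 ± 109 to 11520 ± 198 CPM) and RBCS1B (4342 ± 62.3 to 4021 ± 28.1 CPM), which have close copies that share sequence. With upper-quartile scaling or no rescaling, 11 rose and 3 fell. When single libraries were left out, 11 to 14 photosynthesis genes rose and 2 fell. Camera called the list up (adjusted p = 6.53e-06), with adjusted p = 0.368 with an estimated correlation.

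Flavonoid and anthocyanin genes rose in 4 of 11 cases with 0 falling, in both adjustments (camera adjusted p = 0.0143, and 0.221 as the adjusted p with an estimated correlation). LDOX, a late enzyme gene of the pathway, rose from 14.52 ± 0.822 to 20.61 ± 0.171 CPM, GSTF12 from 16.2 ± 0.07 to 22.1 ± 1.28 CPM and the repressor gene MYBL2 from 27.06 ± 1.84 to 31.87 ± 2.46 CPM. CHS, the entry enzyme gene, rose from 27.75 ± 0.999 to 31.62 ± 1.99 CPM, a call that ended without WT replicate 3 or hrlp-2 replicate 1 (adjusted p up to 0.101). Roots were not harvested, and most root markers were near 0: CASP2 and CASP4 were listed at 0 in all libraries and COBL9 averaged 0.03 CPM in WT. Of the 3 root markers tested, PYK10 rose from 231.6 ± 0.774 to 266.9 ± 7.80 CPM and TIP2;2 from 107.6 ± 2.75 to 134.8 ± 0.376 CPM, while NRT2.1 measured 1.73 and 1.38 CPM (adjusted p = 0.399). Both rises held adjusted over the list alone. Camera called the root markers up at adjusted p = 0.0099, with adjusted p = 0.171 with an estimated correlation and 0.126 without the expression filter.

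**Figure D2:**
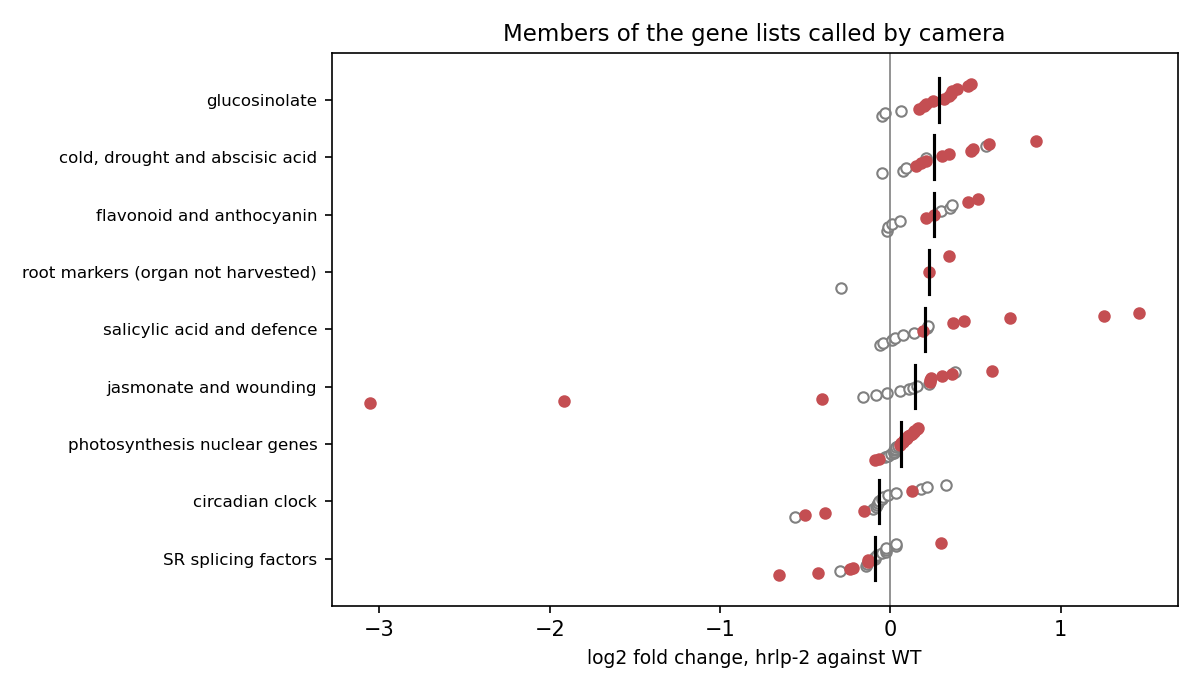
Log2 fold change of hrlp-2 against WT (horizontal axis) for the tested members of the 9 gene lists called by camera (vertical axis). Filled red points passed the test at an adjusted p of 0.05, open points did not, and black bars mark list medians, which run from -0.09 (SR splicing factors) to 0.28 (glucosinolate).

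SR splicing factor genes fell more often than they rose, with 6 falling, 1 rising and 12 of 19 not passing. Adjusted over the list alone, 9 fell and 1 rose. SR34b went from 14.24 ± 0.668 to 8.73 ± 0.789 CPM (1.58-fold lower, adjusted p = 2.42e-06). SR30 went from 43.27 ± 2.97 to 31.65 ± 1.88 CPM (adjusted p = 8.18e-07) and SCL28 from 24.18 ± 0.854 to 20.14 ± 0.468 CPM. SCL30 was the member that rose, from 63.96 ± 2.55 to 77.52 ± 1.88 CPM (adjusted p = 1.25e-06). Camera called the list down (adjusted p = 0.00523), with adjusted p = 0.134 with an estimated correlation. Among 19 hnRNP-like RNA-binding protein genes, 2 rose and 5 fell, and 3 rose and 6 fell adjusted over the list alone. UBA2A fell from 120.2 ± 1.87 to 100.2 ± 0.624 CPM, UBA2B from 31.84 ± 0.248 to 26.71 ± 0.127 CPM and UBA2C from 51.75 ± 1.93 to 43.69 ± 1.70 CPM. RZ-1A rose from 20.6 ± 4.72 to 25.3 ± 3.02 CPM, a call that ended without WT replicate 1 (adjusted p = 0.171), hrlp-2 replicate 3 or the expression filter. The other rise, of UBP1C (48.57 ± 2.13 to 53.62 ± 1.91 CPM), ended without WT replicate 2 (adjusted p = 0.093) or hrlp-2 replicate 3, so that 0 rose and 4 fell without hrlp-2 replicate 3. Camera did not call this list (adjusted p = 0.4), while fry called it down (adjusted p = 0.0245).

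Of 17 tested circadian clock genes, 3 fell and 1 rose, in both adjustments. PRR7, a clock repressor, fell from 145.2 ± 2.06 to 109.4 ± 8.38 CPM (adjusted p = 3.47e-09). LNK2 fell from 35.14 ± 2.87 to 24.24 ± 0.255 CPM (adjusted p = 1.45e-07) and PRR3 from 87.13 ± 1.68 to 76.86 ± 2.38 CPM, while the evening complex gene LUX rose from 98.45 ± 2.76 to 106.0 ± 2.03 CPM. The camera call was down at adjusted p = 0.0469, with adjusted p = 0.221 with an estimated correlation. It ended in 4 fits without 1 library, with adjusted p-values up to 0.0862 (without hrlp-2 replicate 3), and with no expression filter or a stricter one. With upper-quartile scaling, and with the deposited CPM not rescaled, 6 clock genes fell and 1 rose.

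None of the remaining lists that could be tested was called by camera, while fry called the heat shock list down (adjusted p = 0.0367) and by its mixed p shade and elongation growth (0.00908) and the stomatal lineage (0.0241). In the floral organ identity list, too small for a list test, PI fell from 1.64 ± 0.398 to 0.530 ± 0.121 CPM (adjusted p = 0.00108), 1 of 2 members tested. Among shoot meristem and boundary genes, CLV1, a receptor kinase gene of the shoot meristem, rose from 34.51 ± 0.718 to 39.82 ± 2.23 CPM (1 of 5). That list's median (-0.09) and mean (-0.04) were below 0 although its camera direction was up (adjusted p = 0.883), and the median ran from -0.20 to 0.00 when single libraries were left out. In the stomatal lineage, FAMA, which drives guard cell formation, fell from 26.64 ± 0.2 to 22.3 ± 1.097 CPM (1 of 6). In shade and elongation growth, PIF5 rose from 42.26 ± 0.918 to 47.5 ± 0.378 CPM and PIF4 fell from 85.55 ± 0.997 to 78.3 ± 2.82 CPM (1 and 1 of 9), the latter a call that ended in 5 fits without 1 library (adjusted p up to 0.166), with the replicate number as a block, with limma-voom and without the expression filter. SUS1 was the 1 of 8 hypoxia genes that rose (28.54 to 32.05 CPM), a call that ended without hrlp-2 replicate 1 (adjusted p = 0.0628). CYCB1;2 was the 1 of 7 cell cycle genes that rose (19.21 to 21.78 CPM), a call that ended in 4 fits without 1 library (adjusted p up to 0.156) and with upper-quartile scaling, no rescaling or no expression filter. These counts were the same adjusted over the list alone. The 3 heat shock genes tested, HSFA2, HSP90.1 and HSP17.6A, did not pass the limma test (lowest adjusted p = 0.092), though HSP90.1 passed without WT replicate 2. Seed storage and senescence genes had 0 members above the filter and were not tested.

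Called genes did not gather on a chromosome segment. Over 15211 placed nuclear loci, the window of 50 tested loci with the most calls held 19, against a median of 21 in 1000 shuffles (permutation p = 0.99). Within 50 tested loci on each side of HRLP, 16 of 100 were called, against 20.1% elsewhere (two-sided Fisher's exact test p = 0.38).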

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

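The pseudocounts of 0.1 and 1, the deposited CPM without rescaling, the fit without noncoding transcripts and fry's mixed p were chosen after the data were seen. The count-model test planned before the data were examined was not run, because the values are not counts, and the fit without organelle genes was not run, because no such locus was matched. HRLP stayed lower and FLC higher, each past the threshold, in every alternative run. When 1 library was left out, the log2 fold change of HRLP ran from -0.89 to -0.83 and that of FLC from 1.32 to 1.42, genes higher in hrlp-2 from 1634 to 1927, genes lower from 1324 to 1474, and gene lists called by camera from 7 to 10. Of the 9 lists called by camera, 0 were called with a correlation estimated per list, while fry called 14 of the 22 by its directional p and 18 by its mixed p; fry does not compare a list with other genes. The replicate numbers did not pair the samples: deviations of same-numbered libraries correlated at -0.008, -0.016 and -0.026. With the replicate number as a block, 2100 genes were higher and 1697 lower, HRLP was at -0.87 and FLC at 1.39 on the log2 scale, and 9 lists were called. Without the expression filter, 1799 genes were higher and 1419 lower. Rows past 2-fold moved most: 83 higher and 98 lower with limma-voom, 70 higher and 78 lower with a pseudocount of 0.1, 22 lower with a pseudocount of 1, and 23 lower without noncoding transcripts. The last fit leaves out rows that had themselves fallen past 2-fold, such as AT2G08480.1 (-2.65) and AT5G45472.4 (-2.12). At least part of its lower count comes from their removal. Windows of 25 and 100 loci gave permutation p = 0.81 and 0.62. Depth limits weak genes most, since 1 read was worth 0.0397 to 0.0499 CPM.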

Other observations

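All tests in this part except the other splits of the libraries were chosen only after the result was seen, and the expectations for the touch and HRLP tests and for the split of called genes were also written after values bearing on them had been seen. Among 305 families made from shared product descriptions or shared opening letters of gene names, camera called 22 up and 17 down, and 0 were called with an estimated correlation. Rows with ribosomal protein names fell by small amounts. Of 115 rows named RPL, 77 fell and 2 rose (median log2 fold change -0.12, adjusted p = 1.16e-30, and 0.268 as the adjusted p with an estimated correlation), and of 92 rows named RPS, 39 fell and 2 rose (adjusted p = 2.33e-10, and 0.376 as the adjusted p with an estimated correlation). These rows were picked by name alone, so not each of them need be a ribosomal protein gene. Of the RPS rows, 1 rose with upper-quartile scaling or no expression filter, and 1 to 3 rose when single libraries were left out. RPL14A went from 185.8 ± 4.19 CPM in WT to 137 ± 3.66 CPM in hrlp-2 and RPL31C from 444.8 ± 10.6 to 348.3 ± 4.73 CPM (n = 3 each), while RPL34 rose from 326.5 ± 14.8 to 357.4 ± 14.7 CPM. RPL34A, RPL34B and RPL34C fell (log2 fold changes -0.35, -0.20 and -0.22), while RPL17, RPS1 and RPS9B rose like RPL34. Rows were not assigned to the cytosolic, plastid or mitochondrial ribosome, so which of these the falls belong to was not tested. DEAD-box RNA helicase rows named RH fell in 17 of 42 cases and rose in 0, with RH28 at 47.47 ± 0.856 against 33.8 ± 0.369 CPM (family adjusted p = 3.27e-06, and 0.298 as the adjusted p with an estimated correlation).

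Rows named XTH, CML, VHA and NPF rose more often than they fell. Of 21 rows named XTH, xyloglucan-modifying enzymes of the cell wall, 14 rose and 0 fell (adjusted p = 2.72e-11, and 0.268 as the adjusted p with an estimated correlation), including XTH9 (218.5 ± 7.24 to 283.2 ± 4.17 CPM) and XTH7 (207.8 ± 3.55 to 251.5 ± 4.32 CPM). Under the other 3 scalings 13 XTH rows rose. Of 26 calmodulin-like rows named CML, 9 rose and 1 fell, with CML5 going from 18.39 ± 0.873 to 44.69 ± 2.77 CPM, CML23 from 6.01 ± 0.513 to 14.27 ± 1.25 CPM and CML13 falling from 114.7 ± 1.49 to 97.71 ± 2.11 CPM (family adjusted p = 0.000126, and 0.376 as the adjusted p with an estimated correlation). Vacuolar proton pump rows named VHA rose in 11 of 20 cases and fell in 1 (0 without hrlp-2 replicate 1), with VHA-A at 408.6 ± 3.80 against 477.9 ± 9.66 CPM (adjusted p = 3.27e-06, and 0.376 as the adjusted p with an estimated correlation). Transporter rows named NPF rose in 11 of 34 cases and fell in 0, with NPF1.1 at 21.83 ± 0.511 against 27.72 ± 0.624 CPM (adjusted p = 0.000961, and 0.376 as the adjusted p with an estimated correlation).

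With 10 ways to split the 6 libraries into 3 and 3, no share under 0.05 can be reached. The real split gave 3811 called genes and the highest of the others 0, and the real split gave 9 called lists and the highest of the others 3. In each case 1 of the 10 splits, the real one, gave as many.

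Touch-inducible and other rapidly induced genes were higher in hrlp-2, where a list of 26 such genes was written from background knowledge after the rises of XTH22 and CML24 had been seen, and 22 were tested. Without those genes, 10 of 20 rose and 0 fell, and camera gave p = 2.3e-08, or p = 0.0161 with an estimated correlation. The rest of the list was also written after the data were seen, so these p-values are not independent support. They were also not adjusted over the fixed lists or the scanned families. The rises included CML12 (42.48 ± 0.922 to 67.65 ± 1.11 CPM), WRKY33 (6.17 ± 1.03 to 9.36 ± 0.378 CPM) and NHL3 (60.08 ± 3.22 to 83.74 ± 1.90 CPM). The other 10 did not pass the limma test, among them CAM2 (30.83 ± 0.365 to 31.14 ± 2.21 CPM, adjusted p = 0.742), CML38 (adjusted p = 0.744) and WRKY40 (adjusted p = 0.825). The lowest median log2 fold change over 4 scalings was 0.416 for all 22 members and 0.365 for the 20. A scaling factor moves all genes by about the same amount. The list's lead over the other genes was therefore bound to stay, and this check could not test it. Handling at harvest that differed between the groups cannot be told apart from the genotype, because 16 of 22 members, and 14 of the 20, had all 3 hrlp-2 libraries above all 3 WT libraries and both would give this. A different hour of harvest may add to the rise of the list. The median absolute log2 fold change of the clock genes was 0.105, well under the signed median of the list. Single clock genes such as LNK2 and PRR7 moved further than 0.105, so a difference in hour stays open. An effect of hrlp-2 itself was not tested apart from handling or hour.

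Of the 207 rows named RPL or RPS followed by a number, 116 fell and 4 rose (median log2 fold change -0.10). A trend with expression level does not account for it, since in a permutation test 10000 random sets of other genes matched on expression had a median of 0.05 and none was as low (p = 1e-04, the smallest these draws can give). Gene length bias could also lower short genes, but only 36 of these rows had a locus of their own and so a length, under the 80% needed, so that check is void and length cannot be told apart from an effect of the genotype.

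HRLP transcript remained at 53.2% of WT in hrlp-2. Wild-type plants mixed into the mutant harvest could leave such a share, but then no gene could fall further than HRLP did. In all, 21 called genes had an upper 95% bound below the log2 fold change of HRLP, among them PDF1.2C (-3.85, bound -3.46), TAT3 (-1.41, bound -1.05) and AtRLP31 (-1.21, bound -1.01), so mixing does not account for the whole share. That the hrlp-2 allele still makes a transcript, in part or in full, is an open explanation not tested here, since the files hold no reads.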
